A study of Mus musculus with 6 samples.

How the data were processed

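Poly(A) RNA of mouse splenic macrophages was sequenced in 6 libraries, 3 labelled WT and 3 labelled Adap-KO. Per the labels' protocols, RNA was extracted with Trizol, mRNA was taken up on oligo(dT) beads, and libraries were made with a NEBNext Ultra kit and random hexamer priming. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mouse build mm10 were used. The authors deposited 1 table of raw counts per gene with gene positions, biotypes and lengths. Its values are whole numbers with totals that differ between libraries. The strand setting, the handling of reads that map to several places and the annotation release are not given in the sources used here. Reads of near-identical paralogs and of overlapping or antisense genes therefore cannot be assigned with certainty, and their genes are uncertain.

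All 6 columns were matched to samples by name, and groups and replicate numbers came from the sample titles. Of 54532 gene identifiers 54495 were found in GENCODE release M21, 98.3% of them at the same position. It served for GC content, taken from the longest transcript of each gene, and for the names of 27 genes whose symbols had been turned into dates. Lengths were those in the deposited table. Library totals lay between 14951603 and 17415675 counts. Reads carry no molecular identifiers here, so counts are not independent molecules. A chi-square comparison of counts between each pair of libraries gave at least 20.0 per degree of freedom, where counting noise alone gives about 1, so no library was treated as deposited more than once.

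Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 14216 genes. Libraries were scaled by TMM factors, which were 0.83, 0.86 and 0.97 for WT replicates 1, 2 and 3 and 1.11, 1.10 and 1.17 for Adap-KO replicates 1, 2 and 3. The robust quasi-likelihood fit held the group alone, its test was two-sided, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Standard errors were taken as the size of the log2 fold change divided by the square root of the F statistic. CPM are counts normalised to the library total and scaled by TMM factors, given as mean ± SD over 3 libraries. Fold changes are Adap-KO over WT label.

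The 21 gene lists were fixed before the data were examined. They cover Fc gamma receptors and their signalling, phagocytic receptors, ADAP partners and integrin activation, interferon and STAT1 targets, MHC class II presentation, red pulp macrophage identity, inflammatory cytokines, alternative activation, lysosome and phagosome oxidase, cell cycle, 9 other cell types (B, plasma, T and NK, neutrophil, monocyte, dendritic, erythroid, platelet, stromal and endothelial), immediate-early and heat-shock genes and mitochondrially encoded mRNAs. Some genes stand in 2 lists, such as Mrc1 and Klrd1, and macrophages themselves express some markers of other types, such as Cd22, Tfrc and Sdc1. Lists were tested against all other genes with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 and adjusted over the 21 lists. An estimated correlation and fry were the alternatives. Fry asks whether the members of a list change at all, and not whether they change more than other genes. With an estimated correlation 0 of the 21 lists passed, with or without the GC and length correction. The adjusted p-values of camera were tied there, at 0.96 or 0.97 without the correction and 0.99 for all 21 lists with it. They show that no list passed and do not set the lists apart from each other.

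Genes named in the text were set by a rule written before the data were examined. They are Fyb, Stat1, the 4 Fc gamma receptor genes, the 6 largest rises and 6 largest falls among called protein-coding genes without overlap of the groups and with at least 5 CPM in the higher group, up to 3 called members of each list by smallest p, and the most abundant member of a list with none. The largest changes leave out predicted and antigen receptor genes. Other genes are said to have been chosen after their values were seen.

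Alternatives written before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2's size factors in edgeR, library totals alone, TMM without genes of other cell types, no low-count filter, a stricter low-count filter, the replicate number as a block, each library left out in turn, a log2 fold change of at least 1, and leaving out genes within 10 Mb of Fyb. After the data were examined 4 more were added. The first is an offset per gene and library from a smooth of each library's deviation on GC content and log2 length, fitted with mgcv 1.9.3 (basis size 8 per axis) for the 14206 tested genes with a GC content. The second is a covariate, the mean log2 CPM of a list of nuclear-retained long non-coding RNAs. The third leaves out WT replicates 1 and 2 together, so that the lone WT library is assumed to vary like the others. The fourth joins the GC and length correction with an estimated inter-gene correlation. Gene families in the closing section were picked after the data were examined.

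The test was tried on simulated counts with the means and library sizes of these samples and 200 changed genes. Without a trend, over 13825 genes, it recovered 22.4% of genes changed 2-fold, 72.9% of those changed 4-fold and 93.9% of those changed 8-fold, and 3.92% of its calls were on unchanged genes. With a simulated GC trend that differed between the groups, 97.5% of 6587 calls were on unchanged genes, and the correction brought this to 7.89% of 114 calls. That trend was a straight line in the same GC content that the correction uses. It held no length trend and no gradient among libraries of a group. The simulation therefore does not show how well the correction works on these data. Counts per exon and splice junctions were not analysed here. Figures were drawn with matplotlib 3.10.9.

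After the data were examined, the bound that decides whether GC content and length account for the breadth of the difference was rewritten once. The first version asked that at least 50% of the calls be kept (53.4% were), and the second asks that more than 10% of tested genes be called after the correction. Both give the same reading. For nuclear RNA and the guanylate-binding protein genes, the first test asked whether at least 50% of the members passed with the covariate (0 did), which left the cause open because that covariate runs almost fully along the label. It was replaced by the trend among the libraries labelled WT, carried to the level of the others as a straight line. Its bound was written after the values were seen. On the log2 scale it argues against the gradient as the whole cause for that line only, whose error was not estimated.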

Results

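The series measured mRNA in mouse splenic macrophages from animals labelled wild type (WT) and Adap-KO, with 3 libraries per label. ADAP (adhesion and degranulation promoting adapter protein) is a scaffold protein of haematopoietic cells encoded by Fyb, and STAT1 is a transcription factor that carries interferon signals. The series title places both in phagocytosis by macrophages during immune thrombocytopenia, a disease in which antibody-coated platelets are removed, largely in the spleen. The design holds 1 comparison, Adap-KO against WT, and the question it addresses is which transcripts differ in splenic macrophages when ADAP is lost. The deposited table holds raw read counts for 54532 genes, and the totals per library lay between 14951603 and 17415675 counts. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. No pair of libraries agreed within counting noise, and each was counted as 1 replicate.

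The targeted gene was not lower in the libraries labelled Adap-KO. Fyb (ENSMUSG00000022148, mm10 chromosome 15, 6522853 to 6663313, plus strand, protein-coding) had 38.4, 37.7 and 47.8 CPM (read counts normalised to the library total) in WT replicates 1, 2 and 3, and 59.1, 65.7 and 71.0 CPM in Adap-KO replicates 1, 2 and 3. The means were 41.3 ± 5.63 CPM for WT and 65.2 ± 5.96 CPM for Adap-KO (SD, n = 3 each), a log2 fold change of 0.66 with a standard error (SE) of 0.17 and an adjusted p of 0.011 by edgeR's quasi-likelihood test. With a correction for GC content and gene length the log2 fold change was 0.38, with an adjusted p of 0.068. It no longer passed the threshold without Adap-KO replicate 3 either, at an adjusted p of 0.063. The counts cover the whole gene. The part that the allele removes is not given in the sources used here, and counts per exon were not analysed here, so a transcript left by the allele would still be counted. An overlapping pseudogene on the same strand, Gm7666, held 26 to 58 counts per library against 528 to 1341 for Fyb, and an antisense gene, Gm2245, held at most 7. Because Fyb went against the label, groups are called by their labels throughout, and every direction below rests on those labels alone. Stat1 (ENSMUSG00000026104, chromosome 1, 52119440 to 52161865) had 71.5 ± 12.7 CPM in the libraries labelled WT and 74.9 ± 13.4 in those labelled Adap-KO, a difference within the spread between replicates (log2 fold change 0.07, SE 0.20, edgeR adjusted p = 0.80). After the GC and length correction its log2 fold change was −0.64, with an adjusted p of 0.065.

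**Figure D1:**
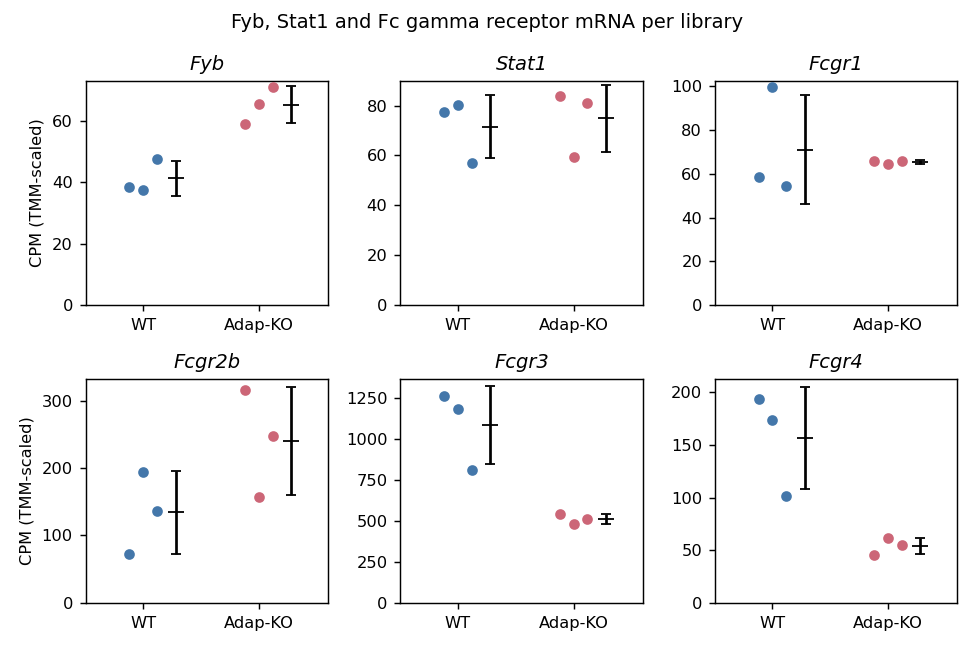
Level of Fyb, Stat1 and the 4 Fc gamma receptor genes, in CPM scaled by TMM factors, in each of the 3 libraries labelled WT (blue) and the 3 labelled Adap-KO (red), with the group mean and SD as black bars. Fyb lay between 37.7 and 47.8 CPM in the libraries labelled WT and between 59.1 and 71.0 in those labelled Adap-KO, whereas Fcgr3 and Fcgr4 were lower in all 3 libraries labelled Adap-KO.

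The libraries also differed in what kinds of RNA they held. In a list of nuclear-retained long non-coding RNAs, set and named after their values were seen, 8 of 9 tested members were higher with the Adap-KO label and 0 lower (median log2 fold change 2.09). After the GC and length correction 4 were higher, and without WT replicates 1 and 2, 5 were. Camera's adjusted p for this list was 0.00027, and 0.32 with an estimated correlation. Malat1, an abundant RNA of nuclear speckles, took 0.0073%, 0.023% and 0.078% of counts in WT replicates 1, 2 and 3, against 0.16% to 0.22% in the libraries labelled Adap-KO. Xist, the RNA that coats the inactive X chromosome, had 946, 936 and 2335 counts in the libraries labelled WT and 21766 to 23979 in those labelled Adap-KO. Neat1 had 201, 1186 and 2890 counts against 11770 to 15451. Genes annotated as sense-intronic took 0.0039 ± 0.0021% of counts with the WT label and 0.015 ± 0.0014% with the Adap-KO label (SD, n = 3 each). Mitochondrially encoded genes took 0.99%, 2.19% and 4.64% in WT replicates 1, 2 and 3 and 5.0%, 7.22% and 6.09% in Adap-KO replicates 1, 2 and 3. The number of genes with at least 1 count was 17804, 19239 and 20652 against 22066 to 22636. On each of these measures WT replicate 3 lay nearest to the libraries labelled Adap-KO.

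**Figure D2:**
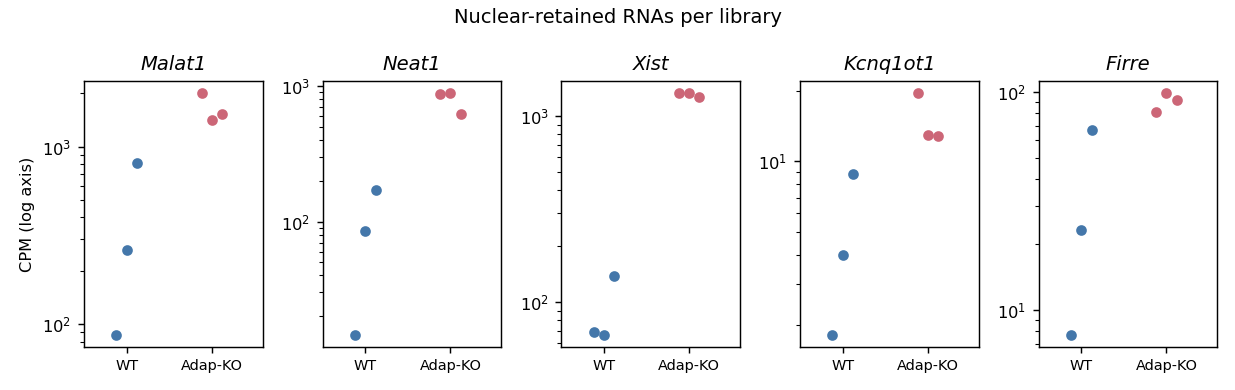
CPM of 5 nuclear-retained RNAs on a log axis, 1 point per library, for the 3 libraries labelled WT (blue, replicates 1 to 3 from left to right) and the 3 labelled Adap-KO (red). All 3 libraries labelled Adap-KO lay above all 3 labelled WT for each RNA, and the libraries labelled WT differed among themselves, with 1201, 3681 and 13616 counts of Malat1.

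Gene expression differed broadly between the labels. Of 14216 tested genes, 7269 (51.1%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3904 higher and 3365 lower in the libraries labelled Adap-KO. Scaling by library totals alone gave 4688 higher and 1581 lower, since it moved the median log2 fold change of tested genes from 0.06 to 0.40. With the GC and length correction 5405 genes passed, 2009 higher and 3396 lower, and 3883 of them had been called in the same direction without it. That correction moved the median log2 fold change of tested genes to −0.15, so the split into higher and lower partly reflects that shift. At a log2 fold change of at least 1 in size, 3244 genes were higher and 1220 lower. The groups did not overlap in 9253 genes (65.1%), where chance gives 10%. The fold change followed GC content and length. Its median was 1.97 on the log2 scale in the decile of genes with the lowest GC content and −0.56 in the decile with the highest (Spearman's rho across genes −0.57 for GC content and 0.30 for length, where genes are not independent replicates). When WT replicates 1 and 2, the libraries with the least nuclear RNA, were both left out, 4981 genes passed, 2871 higher and 2110 lower. With the level of nuclear-retained RNA as a covariate edgeR called 0 genes, and 1397 had an unadjusted p under 0.05. That level lay between 1.81 and 3.89 mean log2 CPM with the WT label and between 5.47 and 5.82 with the Adap-KO label, so the covariate and the label overlap almost fully.

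**Figure D3:**
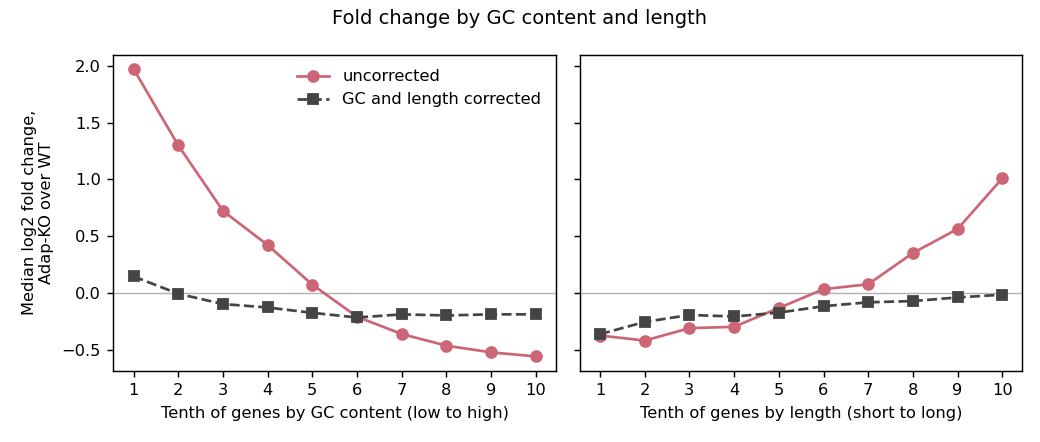
Median log2 fold change, Adap-KO over WT label, in deciles of the tested genes by GC content (left) and by gene length (right), without correction (red circles) and with the GC and length correction (dark squares). Without correction the median went from 1.97 in the lowest GC decile to −0.56 in the highest and from −0.37 in the shortest genes to 1.01 in the longest. With it the GC deciles lay between 0.15 and −0.22, and the length deciles still went from −0.36 in the shortest genes to −0.015 in the longest.

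Among protein-coding genes the largest rises were in genes of lymphocytes and in a muscle gene. Gpr174, a lysophosphatidylserine receptor of lymphocytes, rose from 0.27 ± 0.25 to 8.94 ± 2.81 CPM (log2 fold change 5.02, SE 0.64, edgeR adjusted p = 0.00038). Neb, which encodes the sarcomere protein nebulin, rose 27.2-fold, from 0.35 ± 0.16 to 9.42 ± 3.46 CPM. The T cell development gene Themis rose 26.0-fold, the lymphocyte GTPase gene Gimap8 23.1-fold, the T cell receptor associated adaptor gene Trat1 21.3-fold and the inhibitory receptor gene Btla 21.1-fold. All 6 were under 1 CPM on average with the WT label, so the size of these folds depends on few reads. The largest falls were in Awat1, an acyltransferase gene, from 10.9 ± 4.18 to 1.62 ± 0.81 CPM (log2 fold change −2.75, SE 0.44, edgeR adjusted p = 0.0012), and in the metallothionein gene Mt3, from 39.6 ± 26.0 to 6.74 ± 2.41 CPM. The glutathione transferase gene Gsta2 fell by 2.40 on the log2 scale, the secreted phospholipase gene Pla2g2d by 2.22, Npy, which encodes neuropeptide Y, by 2.20 and the tubulin gene Tubb2b by 2.17. All 12 kept their sign after the GC and length correction, and all but Npy stayed past the threshold (Npy adjusted p = 0.058). WT replicate 1 had the highest CPM of its group for all 6 genes that fell, with 51.8 CPM of Gsta2 against 15.9 and 10.06 in replicates 2 and 3, and 189 of Npy against 73.5 and 40.2. Gsta2 and Npy passed in the same direction in 10 of 16 alternatives each. Without WT replicates 1 and 2 all but Awat1 lost the threshold, with Gsta2 at −1.05 (adjusted p = 0.41) and Npy at −0.88 (0.44), and with the nuclear RNA covariate Gsta2, Npy, Mt3 and Tubb2b turned positive, at adjusted p of 0.82 to 0.85.

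Receptors for antibody-coated particles did not move together. Fcgr4, an activating Fc gamma receptor gene, fell from 157 ± 48.5 CPM in the libraries labelled WT to 54.1 ± 7.95 in those labelled Adap-KO (log2 fold change −1.53, SE 0.25, edgeR adjusted p = 0.0015). Fcgr3, another activating receptor gene, fell from 1084 ± 239 to 512 ± 31.4 CPM (log2 fold change −1.08, SE 0.21, edgeR adjusted p = 0.0031). The inhibitory receptor gene Fcgr2b had 134 ± 61.3 and 240.4 ± 79.7 CPM and did not pass (log2 fold change 0.84, SE 0.37, edgeR adjusted p = 0.084). It was called higher in 5 alternatives, namely DESeq2 (adjusted p = 0.034), library totals alone (0.042), no low-count filter (0.0012), and without WT replicate 2 (0.036) or Adap-KO replicate 2 (0.043), and with the GC and length correction its log2 fold change was 0.04. The high-affinity receptor gene Fcgr1 had 71.1 ± 25 and 65.5 ± 0.76 CPM and did not pass (log2 fold change −0.12, SE 0.23, edgeR adjusted p = 0.69). Both falls held with the GC and length correction, at −1.68 for Fcgr4 and −1.05 for Fcgr3, and without WT replicates 1 and 2 they were −0.92 and −0.67. With the nuclear RNA covariate they were −0.22 and −0.23, with adjusted p of 0.92 and 0.90. In the list of 24 Fc gamma receptor and signalling genes 2 rose and 11 fell, and 13 passed when adjusted over the list alone. The number that fell was 3 without Adap-KO replicate 3, 4 without Adap-KO replicate 1 and 6 without Adap-KO replicate 2. Those that rose were Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, with a log2 fold change of 1.97, and Vav3, an exchange factor for Rho GTPases, with 1.71. The Src-family kinase gene Hck, chosen after its values were seen, fell by 1.15. The list as a whole did not pass limma's camera (median log2 fold change −0.27, adjusted p = 0.21). Its median was 0.08 with library totals alone, with 4 members higher and 3 lower, and the GC and length correction left 2 higher and 5 lower.

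Phagocytic, scavenger and complement receptor genes moved in both directions. Of 28 tested members 8 rose and 11 fell, and 22 passed when adjusted over the list alone. With library totals alone 9 were higher and 7 lower, with a median log2 fold change of 0.46. Without WT replicate 2, or without any single library labelled Adap-KO, 5 rose. The scavenger receptor gene Msr1 was 3.43-fold higher with the Adap-KO label, at 160.5 ± 6.14 and 550 ± 51.9 CPM (log2 fold change 1.78, SE 0.17, edgeR adjusted p = 7.1e-05). It has a GC content of 38.4%, and its corrected log2 fold change was −0.21, with an adjusted p of 0.41. Mfge8, which encodes a bridging protein between apoptotic cells and integrins, fell from 1438 ± 376 to 508 ± 66.1 CPM and still fell after the correction (log2 fold changes −1.502 and −1.24). The lipoprotein receptor gene Scarb1 fell by 1.29 on the log2 scale, and by 1.83 after the correction. The list did not pass camera (adjusted p = 0.40). Its median was 0.13 and its mean 0.01, whereas camera's direction was down, and the correction turned the median to −0.52 with 0 members higher and 7 lower.

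Interferon and STAT1 target genes were called mainly in the upward direction. Of 46 tested members 14 rose and 3 fell, and 16 passed when adjusted over the list alone. Among all 14216 tested genes 51.1% passed, 3904 higher and 3365 lower, so the number of rises alone does not show a rise particular to this list. Gbp4, an interferon-induced GTPase gene, rose from 6.24 ± 0.91 CPM with the WT label to 85.3 ± 31.4 with the Adap-KO label (log2 fold change 3.77, SE 0.31, edgeR adjusted p = 4.3e-05). Its relative Gbp7 rose 8.46-fold, from 10.03 ± 2.67 to 84.7 ± 16.6 CPM, and the antiviral gene Trim30a rose 4.82-fold, from 17.2 ± 2.51 to 83.2 ± 3.18 CPM. After the GC and length correction the log2 fold changes were 2.32 for Gbp4, 1.55 for Gbp7 and 0.79 for Trim30a, all past the threshold. Members of such paralog families can share reads, so the level of a single Gbp gene is uncertain. The 3 that fell, named after their values were seen, were Oas1a, an antiviral synthetase gene (−1.15), the tetherin gene Bst2 (−1.16) and the immunoproteasome gene Psmb8 (−0.66), and 6 members fell without WT replicate 3. The list did not pass camera (median log2 fold change 0.32, adjusted p = 0.21). Camera's adjusted p was 0.0047 without Adap-KO replicate 2, 0.0030 without WT replicates 1 and 2 and 0.044 with the GC and length correction, where 14 members were higher and 2 lower while the median was −0.07. With an estimated correlation the adjusted p was 0.96, and 0.99 with both the correction and an estimated correlation.

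Lysosomal genes fell together. Of 29 tested genes of lysosomes and the phagosome oxidase 20 fell and 1 rose in the libraries labelled Adap-KO, with a median log2 fold change of −1.10, and 22 passed when adjusted over the list alone. The list passed camera (adjusted p = 2.1e-05), and its call was lost with an estimated correlation (adjusted p = 0.96, a value tied with most other lists). Ctsd, which encodes the lysosomal protease cathepsin D, fell from 17474 ± 2509 to 6066 ± 1172 CPM (log2 fold change −1.53, SE 0.25, edgeR adjusted p = 0.0013). The acid glucosidase gene Gaa fell from 358 ± 53.3 to 156 ± 4.18 CPM, and Cyba, a membrane subunit of the phagosome oxidase, from 2098 ± 586 to 766 ± 13.1 CPM. The gene that rose, named after its values were seen, was Cybb, the catalytic partner of Cyba, at a log2 fold change of 1.27, which was −0.06 after the GC and length correction. With that correction 23 members were lower and 1 higher, and camera's adjusted p was 8.3e-07, or 0.99 with an estimated correlation. With the nuclear RNA covariate the list's median was −0.32 and its camera adjusted p 0.063.

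Genes of red pulp macrophages, the splenic macrophages that recycle iron from red blood cells, also fell. Of 24 tested members 14 fell and 1 rose, with a median log2 fold change of −0.89, and 16 passed when adjusted over the list alone. With library totals alone 9 were lower and 1 higher, with a median of −0.55. Camera's adjusted p was 0.0024, and it was 0.96 with an estimated correlation. Limma's fry did not call the list (adjusted p = 0.12). Ftl1, the ferritin light chain gene, fell from 11810 ± 2761 to 4457 ± 290 CPM (log2 fold change −1.41, SE 0.24, edgeR adjusted p = 0.0019). The haem-binding protein gene Hebp1 fell from 111 ± 21.6 to 47.3 ± 8.56 CPM. The transcription factor gene Maf went the other way, from 39.5 ± 12.3 to 115 ± 23.7 CPM. The GC and length correction left 9 members lower and 1 higher (camera adjusted p = 0.012, or 0.99 with an estimated correlation), and with the nuclear RNA covariate camera's adjusted p was 0.11. WT replicate 3 had the lowest CPM of its group for Ctsd, Cyba and Ftl1, and the highest level of nuclear RNA.

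Partners of ADAP and genes of integrin activation split. Of 23 tested members 7 rose and 5 fell, 14 passed when adjusted over the list alone, and camera's adjusted p was 0.83, whereas fry called the list in the upward direction (0.034). The integrin gene Itga4 rose 7.42-fold, from 16.3 ± 5.06 to 121 ± 30.3 CPM. The small GTPase gene Rap1a was 3.0-fold higher and the adaptor gene Nck1 2.05-fold higher. After the GC and length correction the log2 fold change was 0.89 for Itga4, −0.14 for Rap1a and −0.72 for Nck1, the last past the threshold in the other direction. The 5 that fell, named after their values were seen, were the integrin genes Itgb2 and Itgb3 (both −0.90), the kindlin gene Fermt3 (−0.63), the talin gene Tln1 (−0.56) and the actin regulator gene Evl (−0.56). The number that fell was 1 without Adap-KO replicate 1 or 3 and 2 without WT replicate 1. With the correction 1 member was higher and 4 were lower. Of these 5 Itgb2 alone passed with library totals alone, and none passed with the correction, at adjusted p from 0.060 for Itgb2 to 0.65 for Evl.

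Inflammatory and NF-kB target genes rose in 10 of 27 tested members and fell in 3, and 13 passed when adjusted over the list alone (median log2 fold change 0.53, camera adjusted p = 0.41). Ptgs2, the inducible prostaglandin synthase gene, rose from 1.19 ± 0.14 to 13.1 ± 5.87 CPM. The cytokine gene Il1a rose 5.48-fold, from 21.2 ± 4.84 to 116 ± 54.0 CPM, and the chemokine gene Ccl2 2.28-fold. After the GC and length correction 6 members were higher and 2 lower, Ptgs2 and Il1a stayed past the threshold at 1.82 and 1.18, and Ccl2 did not (adjusted p = 0.051). Those that fell, named after their values were seen, were Cd14 (−0.83), Cebpb (−0.82) and Il1rn (−1.14), of which Il1rn alone passed with the correction. With library totals alone 11 members were higher and 0 lower, these 3 at adjusted p of 0.098 to 0.13. The number that fell was 1 without Adap-KO replicate 2 or 3 and 5 without WT replicate 3. Genes of alternative activation showed 2 rises and 1 fall among 15, and 3 passed when adjusted over the list alone (median 0.27, camera direction down, adjusted p = 0.82). The mannose receptor gene Mrc1 was 2.92-fold and the cytokine signalling gene Socs2 2.40-fold higher, neither past the threshold after the correction, and Tgfb1 fell from 653 ± 132 to 345 ± 49.1 CPM. The median of this list was −0.62 without Adap-KO replicate 1, with 3 falls, and −0.04 without WT replicate 1 or with the replicate number as a block. There were 2 falls without WT replicate 3. Genes of MHC class II presentation and costimulation showed 2 rises and 1 fall among 14, with 3 past when adjusted over the list alone (median −0.45, camera adjusted p = 0.58). The costimulatory genes Cd80 and Cd86 had log2 fold changes of 1.27 and 0.81, and H2-DMb1, a chaperone of peptide loading, −0.87, and none of these passed with the correction. The fall count was 0 without WT replicate 2, Adap-KO replicate 2 or Adap-KO replicate 3, and 2 without WT replicate 1 or 3, and the median was 0.06 without WT replicate 2.

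Cell cycle genes rose in 6 of 26 members and fell in 4, and 9 passed when adjusted over the list alone. The proliferation marker gene Mki67 rose from 11.7 ± 1.29 to 136 ± 26.5 CPM (log2 fold change 3.53, SE 0.21, edgeR adjusted p = 2.1e-05). The mitotic genes Bub1 and Kif11 rose 8.68-fold and 7.93-fold, and all 3 stayed past the threshold with the GC and length correction, at 2.56, 1.65 and 1.69. The 4 that fell, named after their values were seen, were E2f1 (−0.65), Ccne1 (−0.81), Mcm2 (−0.54) and Ube2c (−0.74), and none of them passed with library totals alone. The number that fell was 0 without WT replicate 1, Adap-KO replicate 1 or Adap-KO replicate 2, 2 without WT replicate 2 or Adap-KO replicate 3, and 9 without WT replicate 3. The list's median was −0.20 and its mean 0.31, camera's direction was up with an adjusted p of 0.87, and the median was 0.17 with library totals alone. With the nuclear RNA covariate the median was 0.56 and camera passed in the upward direction (adjusted p = 6.8e-06).

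**Figure D4:**
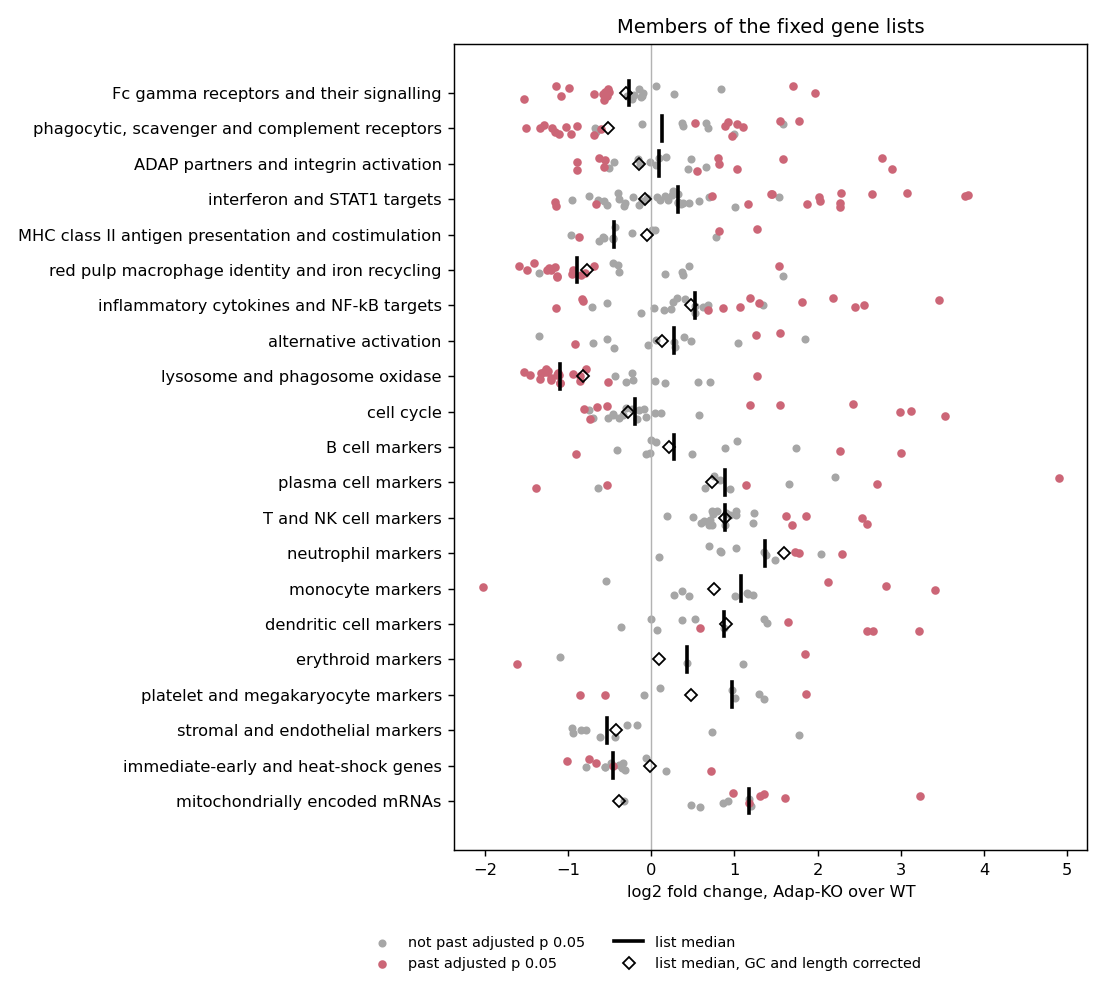
Log2 fold change, Adap-KO over WT label, of each tested member of the 21 fixed gene lists, in red where the adjusted p was under 0.05 and grey otherwise, with the list's median as a black bar and its GC and length corrected median as an open diamond. The lysosome list (median −1.10, corrected −0.82) and the red pulp macrophage list (−0.89, corrected −0.78) lay to the left, and mitochondrially encoded mRNAs went from 1.17 to −0.39 with the correction.

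Marker genes of other splenic cell types were mostly higher where they passed. Over all 14216 tested genes 51.1% passed, 3904 higher and 3365 lower, so the marker counts alone do not show a rise particular to markers. For T and NK cells 5 of 22 markers rose and 0 fell, with a median log2 fold change of 0.89, but 1 passed when adjusted over the list alone. Without Adap-KO replicate 3 the count was 1, without Adap-KO replicate 1 or 2 it was 3, and the median lay between 0.45 and 1.49 with single libraries left out, where camera passed without WT replicate 2 (adjusted p = 0.029). With the nuclear RNA covariate the median was −1.13 and camera passed in the downward direction (adjusted p = 0.043). The T cell genes Cd28 and Bcl11b rose 5.78-fold and 3.64-fold, to 23.0 ± 1.11 and 21.99 ± 5.17 CPM, and the NK cell receptor gene Klrd1 had 0.32 ± 0.28 and 2.04 ± 0.82 CPM. Eomes (1.62) and Cd8a (1.69), named after their values were seen, also rose. Dendritic cell markers rose in 5 of 13 and fell in 0, with 4 past when adjusted over the list alone, and 3 rose without Adap-KO replicate 3. Clec9a, a receptor gene of cross-presenting dendritic cells, rose from 4.34 ± 2.59 to 27.9 ± 1.61 CPM, Dpp4 rose 9.33-fold, and Tcf4 was 3.13-fold higher but had a corrected log2 fold change of −0.58. The remaining ones were Klrd1 and Zbtb46 (0.58), the latter named after its values were seen. Monocyte markers rose in 3 of 12, namely Vcan (10.7-fold), Ccr2 (7.10-fold) and F13a1 (4.36-fold), with 3 past when adjusted over the list alone, and Ace, named after its values were seen, fell by 2.02, a call lost without any single library labelled Adap-KO or without WT replicate 2. Neutrophil markers rose in 3 of 12 and fell in 0, with 0 past when adjusted over the list alone. They were Elane, Prtn3 and Mpo, at 1.57 to 2.46 CPM with the Adap-KO label. None rose without Adap-KO replicate 3, and 7 did without Adap-KO replicate 2, where camera passed (adjusted p = 0.033). Leaving out any other single library gave 2.

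Plasma cell markers rose in 3 of 12 and fell in 2, with 5 past when adjusted over the list alone. With single libraries left out 2 to 5 rose, 5 without WT replicate 2 and 2 without WT replicate 3, Adap-KO replicate 2 or Adap-KO replicate 3. The fall count was 1 without WT replicate 2 or without any single library labelled Adap-KO. Of the immunoglobulin constant genes in the list Ighg2b and Ighg2c alone passed, with Ighg2b at 1.5 ± 0.92 and 45.6 ± 19.0 CPM and Ighg2c at a log2 fold change of 2.72. Ighg2c and Xbp1 were named after their values were seen. Prdm1 rose 2.20-fold, whereas Sdc1 fell from 526 ± 243 to 201 ± 32.1 CPM and Xbp1 by 0.53. B cell markers rose in 2 of 12, Ebf1 and Pax5, both under 3 CPM, and Cd22 fell from 139 ± 16.8 to 74.4 ± 3.81 CPM, with 3 past when adjusted over the list alone. Without Adap-KO replicate 2 or 3, 1 rose, without WT replicate 1 or 2, 3 did, and the list's median of 0.27 was −0.05 without WT replicate 1. Erythroid markers showed 1 rise, Tfrc (3.61-fold, corrected log2 fold change 0.10), and 1 fall, Car2 (−1.62), among 5, and both passed when adjusted over the list alone. Car2 had 447 CPM in WT replicate 1 against 152 and 109 in replicates 2 and 3. It passed in the same direction in 10 of 16 alternatives, lost the threshold without any single library labelled Adap-KO (adjusted p of 0.059 to 0.070), and fell by 0.51 without WT replicates 1 and 2. Platelet markers showed 1 rise, Gp5, at 1.0 CPM with the Adap-KO label, and 2 falls, Vwf (−0.86) and Clec1b (−0.56), among 9, all 3 past when adjusted over the list alone. Without WT replicate 3, 4 rose, and without any single library labelled Adap-KO 0 did. Only 1 fell without WT replicate 1, Adap-KO replicate 1 or Adap-KO replicate 3. Clec1b passed in 10 of 16 alternatives, and its log2 fold change was −2.60 with the GC and length correction. No stromal or endothelial marker of 10 passed by edgeR, over all genes or over the list alone. Without Adap-KO replicate 2, 1 passed in each direction, and without WT replicate 2, 1 was lower. The highest of these, Stab2, had 72.4 ± 27.4 and 42.0 ± 20.2 CPM. None of these 9 lists passed camera in the main fit. The T and NK cell list passed in the upward direction with limma-voom (adjusted p = 0.040) and without the low-count filter (0.043). With the nuclear RNA covariate the B cell (0.027), T and NK cell (0.043), monocyte (0.027) and platelet (0.026) lists passed in the downward direction. After the GC and length correction the T and NK cell (adjusted p = 0.0094), neutrophil (0.016) and plasma cell (0.044) lists did, each in the upward direction, and all 3 calls were lost with an estimated correlation (adjusted p = 0.99).

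For signs of RNA quality and handling, 6 of 13 mitochondrially encoded mRNAs rose and 0 fell, with a median log2 fold change of 1.17, a camera adjusted p of 0.25 and 3 past when adjusted over the list alone. Without WT replicate 3, 10 rose, without WT replicate 1, 4 did, and without any other single library 3 did. With the replicate number as a block 8 rose and camera passed in the upward direction (adjusted p = 0.0079). The subunit gene mt-Nd5 had 1590 ± 629 and 3589 ± 668 CPM, mt-Nd6 319 ± 141 and 970 ± 222, and mt-Nd4l 4.76 ± 3.58 and 45.2 ± 32.3. With the GC and length correction 1 was higher and 2 were lower, and the median was −0.39. Immediate-early and heat-shock genes fell in 4 of 15 and rose in 1, with 3 past when adjusted over the list alone (median −0.46, camera adjusted p = 0.21). None rose without WT replicate 2, WT replicate 3 or any single library labelled Adap-KO. With library totals alone 1 was higher and 1 lower. The number that fell was 7 without WT replicate 1, where camera passed (adjusted p = 0.040), and 2 without Adap-KO replicate 2 or 3. Camera passed for it without the low-count filter (adjusted p = 0.043), without WT replicates 1 and 2 (0.034) and, like the mitochondrially encoded mRNAs (9.6e-05), with the nuclear RNA covariate (0.00079), in the downward direction. Jund fell by 1.01, Dnajb1 by 0.75, Atf3 by 0.66 and Dusp1 by 0.46, and Hsph1 rose by 0.71, the last pair named after their values were seen. Of these Jund alone passed with the correction.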

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

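The alternatives for GC content and length, nuclear RNA and the left-out pair of WT libraries were chosen after the data were examined, and the others before. The count of 7269 genes stayed between 5124 and 8379 over all settings with 3 exceptions. These were a log2 fold change of at least 1 (4464), WT replicates 1 and 2 left out (4981) and the nuclear RNA covariate, with which edgeR called 0 genes and 1397 had an unadjusted p under 0.05. That covariate runs almost fully along the groups, so it leaves little to test. DESeq2 called 7470 and limma-voom 7591. Leaving out single libraries gave 5124 to 8379, and leaving out genes within 10 Mb of Fyb 7231. The replicate block called 6387, and same-numbered libraries did not deviate together across genes (correlations −0.05, −0.26 and 0.10), so the numbers are not taken as pairs and not every library correlated best with its own number.

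The log2 fold change of Fyb stayed positive under every setting. It lost the threshold with the GC and length correction (0.38), the nuclear RNA covariate (0.30) and WT replicates 1 and 2 left out (0.44), and lay between 0.58 and 0.74 with single libraries left out, where the adjusted p without Adap-KO replicate 3 was 0.063. The number of fixed lists past the threshold, 2 here, was 6 without the low-count filter, 6 with the GC and length correction, 8 with the covariate, 4 without WT replicates 1 and 2, 0 with an estimated correlation, alone or joined to the GC and length correction, and 2 to 4 with single libraries left out, 4 being without Adap-KO replicate 2. Fry called 3 lists at an adjusted p of 0.034, lysosome (down), ADAP partners (up) and dendritic cell (up), and did not call the red pulp macrophage list (0.12). Unlike camera, fry does not set a list against other genes. The interferon and STAT1 list passed camera in the upward direction without the low-count filter (median 0.27), with the covariate (1.31) and without Adap-KO replicate 2 (0.51). It also passed upward with the GC and length correction, although its median turned negative there (−0.074). The median was 0.85 without WT replicates 1 and 2, and lay between 0.068 and 0.51 with single libraries left out. The adjusted p of the interferon and STAT1 list ranged from 1.4e-11 to 0.73 over the camera fits at the preset correlation. The Fc gamma receptor median turned positive with library totals alone (0.079), and the list passed camera in the downward direction without the low-count filter (median −0.31). That list's adjusted p ranged from 0.028 to 0.63 over the camera fits at the preset correlation, and was 0.96 with an estimated correlation. The phagocytic receptor median turned negative with limma-voom (−0.33), the replicate block (−0.29), the GC and length correction (−0.52) and the covariate (−0.33), and ranged from −0.60 to 0.48 with single libraries left out. Its lowest value came without Adap-KO replicate 2, and it was −0.08 without WT replicate 2. The cause was not tested for any of these.

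Over 76 other named genes and 17 settings, 1109 of 1290 values kept their direction and side of the threshold, 142 lost it, 8 gained it (5 for Fcgr2b and 3 for Stab2) and 31 changed sign. The GC and length correction is built to remove what follows those properties, though a trend with length remained. With it the sign changed for Msr1 (−0.21), Rap1a (−0.14), Tcf4 (−0.58), Nck1 (−0.72), Cd86 (−0.19), mt-Nd5 (−0.60), Fcgr1 (0.18) and Stat1 (−0.64). With the nuclear RNA covariate it changed for Dpp4 (−0.074), Prdm1 (−0.019), Mt3 (0.58), Sdc1 (0.31), F13a1 (−0.76), Ccr2 (−0.34), Tubb2b (0.70), Dnajb1 (0.030), Socs2 (−0.090), Ebf1 (−0.33), mt-Nd5 (−0.25), Pax5 (−0.64), Npy (1.14), Car2 (1.35), Gsta2 (1.17), Bcl11b (−0.56), Fcgr2b (−0.36) and Fcgr1 (0.054). Fcgr1 also changed sign with library totals alone (0.24) and without WT replicates 1 and 2 (0.26), and with single libraries left out it ranged from −0.31 to 0.18 and Stat1 from −0.11 to 0.20. Fcgr1 and Stat1 passed in none of these. Markers under 3 CPM, such as those of neutrophils, rest on few reads at this depth.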

Other observations

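All tests below were chosen after the data were examined, except the splits of the libraries and the test of genes near Fyb.

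Gene families outside the fixed lists, picked by symbol, also differed in the libraries labelled Adap-KO, although none passed camera with an estimated correlation. Of 77 ribosomal protein genes 66 fell and 0 rose (median log2 fold change −0.86), and of 85 nuclear-encoded subunits of the respiratory chain and ATP synthase 67 fell and 2 rose (−1.02). Proteasome subunit genes fell in 24 of 39 and rose in 2 (−0.65), and glutathione transferase genes fell in 8 of 17 and rose in 1 (−0.90). Splicing factor genes of the SR and hnRNP families went the other way, with 24 of 30 higher and 1 lower (1.62), as did zinc finger genes named Zfp, with 181 of 311 higher and 14 lower (1.28). With library totals alone 39 ribosomal protein genes were lower and 1 higher, 56 respiratory chain genes lower and 2 higher, 14 proteasome genes lower and 5 higher, 4 glutathione transferase genes lower and 1 higher, 24 splicing factor genes higher and 0 lower, and 198 zinc finger genes higher and 3 lower. The medians kept their sign with that scaling, at −0.50, −0.66, −0.29, −0.55, 1.94 and 1.61 in this order, and with the GC and length correction, at −0.66, −0.91, −0.69, −0.66, 0.23 and 0.36. That correction left 52 ribosomal protein genes lower and 0 higher, 73 respiratory chain genes, 27 proteasome genes and 8 glutathione transferase genes lower and 0 of each higher, 14 splicing factor genes higher and 3 lower, and 73 zinc finger genes higher and 22 lower. Camera's adjusted p at the preset correlation was at most 0.0066 for each of these families. With an estimated correlation it was 0.32, a tied value that does not set these families apart. Gimap genes, GTPases of lymphocytes, rose in 3 of 8 and fell in 0 (median 1.33). Their camera adjusted p was 0.065 at the preset correlation, 0.0055 with the GC and length correction and 0.52 with an estimated correlation.

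The 4 Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y had 0 counts in all 6 libraries, and Xist was present in all 6.

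The first pattern is the breadth of the difference, with 7269 called genes. GC content and gene length alone are argued against as the whole cause, since 5405 genes were still called after their correction. However, the 2 properties account for 39.5% of the variance of the fold change. The correction also left a trend with length, from a median of −0.36 in the decile of shortest genes to −0.015 in that of the longest. Some of the remaining calls may therefore still follow length. A gradient among the libraries labelled WT, ordered by nuclear RNA, fits what was seen. The difference between the libraries labelled Adap-KO and 1 library labelled WT correlated across genes with the difference between the other 2 libraries labelled WT. The correlations were 0.44, 0.46 and 0.11 (median 0.44), and 0.33, 0.54 and 0.33 after the GC and length correction. The matching values among the libraries labelled Adap-KO were 0.13, −0.05 and −0.21 and give it no support. Their nuclear RNA level spans 5.47 to 5.82 mean log2 CPM, against 1.81 to 3.89 with the WT label. The mitochondrial share (0.99%, 2.19% and 4.64%) and the TMM factors (0.83, 0.86 and 0.97) order WT replicates 1, 2 and 3 in the same way. The test therefore does not single out nuclear RNA, and unspliced RNA was not measured as such. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05, and the real split, 1 of the 10, called 7269 genes while the highest of the others called 0. An effect of the genotype stays open and untested, since nuclear RNA content and label go together in these libraries, and a difference in extraction, cell state or cell mixture may lie behind the gradient.

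The second pattern is that Fyb was higher with the Adap-KO label. Labels swapped between the groups, with a knockout that removes the transcript, are argued against, since the lower group mean was 63.3% of the higher. GC content and length cannot be told apart from a real rise. The corrected log2 fold change was 0.38 with a 95% interval of 0.05 to 0.71 and an edgeR adjusted p of 0.068. Before the correction it was 0.66 with an interval of 0.27 to 1.05. The call ended because the estimate shrank while its SE stayed similar (0.17 before and 0.15 after). The correction also moved the median log2 fold change of all tested genes from 0.06 to −0.15, so part of the shrinkage may be a general shift. A knockout allele that leaves most of the transcript in place, and libraries in which the gene was not lost, both stay open, since counts per exon were not analysed here. Within 10 Mb of Fyb 32 of 48 tested genes were called against 51.1% elsewhere (odds ratio 1.92, 95% interval 1.02 to 3.74, Fisher's exact two-sided p = 0.042). Fyb itself is among these called genes, and the interval starts close to 1. With the GC and length correction the odds ratio was 0.81 (0.42 to 1.53), so variants carried along with a targeted locus can be neither seen nor excluded.

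The third pattern is the guanylate-binding protein genes, interferon-induced GTPases, of which 8 of 9 rose and 0 fell (median log2 fold change 3.08), the exception being Gbp2 at 134 and 154 CPM (0.20, edgeR adjusted p = 0.76). GC content and length are argued against as the whole cause, since 8 members were still called and higher after the correction (median 1.82). A mere shift of reads between paralogs is argued against for the family as a whole. Its summed CPM rose 3.27-fold, from 189 ± 64.7 to 620 ± 194 (SD, n = 3 each), without overlap. The sum cannot tell how many members rose, since reads of 1 higher member may be counted for others. For a straight line on the log2 scale, the nuclear RNA gradient is argued against as the whole cause by the bound set for it. The trend on nuclear RNA among the 3 libraries labelled WT was carried to the level of those labelled Adap-KO. It gave a median log2 change of 0.089, and all 9 members fell short of their fold change (median shortfall 2.19, SD 0.98 over members). The median member's share of the CPM difference was 6.09%, but shares ran from −2199% for Gbp2 to 113% for Gbp2b. No error was estimated for this line through 3 libraries, and members may share reads, so another slope or shape is not excluded. Without WT replicates 1 and 2 the median log2 fold change was 2.77. A share of the rise may still follow the gradient. Gbp2b, Gbp8 and Gbp9 rose most along it among the libraries labelled WT (1.59, 1.45 and 1.76 when carried over). Gbp2, Gbp4, Gbp5 and Gbp7 fell along it (−1.98, −0.12, −0.48 and −0.91). For Gbp2b, at 0.23 and 1.45 CPM, the line gave more than its whole CPM difference. With the nuclear RNA covariate its log2 fold change was −0.02, while 8 of 9 members were above 0 (median of the family 2.15). Of these, 7 had an unadjusted edgeR p under 0.05, and 0 passed when adjusted. A change in interferon response or in cell mixture between the labels may be a candidate explanation, and both stay open, found in these same data and not tested apart. Stat1 itself differed by less than the spread between replicates, and in the wider interferon and STAT1 list 14 members were higher and 2 lower after the correction, with a median of −0.07 and a camera adjusted p of 0.044 in the upward direction, or 0.99 with an estimated correlation.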
